A study of Mus musculus with 3 samples.

How the data were processed

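RNA was sequenced from macrophages of the mouse heart, liver and kidney, with 1 library for each tissue. The labels give a sort by flow cytometry and amplification of total RNA with a kit for low input, followed by Illumina libraries. CASAVA, STAR and the genome build mm10 come from the submitters' processing notes, and their versions and settings are not given in the sources used here.

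The deposited values are RPKM, reads per kilobase of exon per 1000000 reads counted, made by the authors for 34711 RefSeq transcripts. Per the file headers they were computed with the HOMER program analyzeRepeats.pl, which counted reads over exons on both strands, with a total of 1000000 per library and the option -pc 3, a limit of 3 on the tags counted at a position. The column names call these values FPKM, while the command line in the header asks for RPKM. In each library RPKM times exon length in kilobases summed to 1000000 over all transcripts, with the isoforms of a gene counted separately. Since reads were counted on both strands, a gene that overlaps another on the opposite strand cannot be separated from it, and the percent of exon bases shared with another gene was taken from the GENCODE M21 annotation. A limit of 3 tags would remove repeated reads and compress the values of genes densely covered with reads. The unit was assumed when the comparisons were planned and was checked against these sums.

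Low RPKM values times exon length were multiples of a step in each library, which gave the number of reads. All low values checked, those of up to 500 reads, lay within 0.1 of a whole read (15236 in the heart, 12075 in the liver and 14159 in the kidney library). The depth so recovered was 14460617 reads for the heart, 16743421 for the liver and 15550840 for the kidney library, and after keeping 1 transcript per gene 8751978, 10373696 and 9485368 reads. The counts over all transcripts take a read again for each isoform it touches, and per the header all were made under the limit on tags. A floor of 3 reads on 2000 bp of exon corresponded to 0.104, 0.0896 and 0.0965 RPKM. The 100 genes with the most reads took 15.9%, 12.98% and 13.6% of the reads.

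For each of 24453 gene symbols the longest coding RefSeq transcript was kept, or the longest noncoding transcript where there was no coding one, which chose among several for 5612 genes. Genes with RPKM of at least 1 in at least 1 library were compared, 11482 in all. The difference between libraries was taken on log2(RPKM + 1), and at least 2 log2 units, 4-fold on this scale, counted as higher or lower. With 1 library per tissue no test across animals was possible, and neither p-values nor standard errors are given. Intervals of RPKM are exact 95% Poisson intervals from the recovered reads, and intervals of ratios come from the exact 95% Clopper-Pearson interval of the share of reads in either library. Folds printed for a gene are ratios of RPKM without a pseudocount, and with 0 reads in the lower library a fold is a lower bound against 3 reads.

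Gene lists, 38 in all with 654 symbols, were fixed before the data were examined, and 4 symbols were not found. They covered pan-macrophage genes, genes of Kupffer cells, of resident cardiac and interstitial macrophages and of monocytes, genes associated with CX3CR1 and microglia, and macrophage transcription factors. Functional lists were MHC class II, type I interferon, EGF receptor ligands, other growth factors, inflammatory mediators, chemokines, immediate early and heat shock genes, iron and heme, lipids, scavenger and Fc receptors, complement, matrix remodelling, cell cycle, pattern recognition, glycolysis, oxidative phosphorylation, ribosomal proteins and housekeeping genes. A further 13 lists held genes of other cells that a sort could carry along, and 1 list held sex-linked genes. Some symbols stand in several lists. For each list with at least 5 genes compared, the median difference was placed among those of 10000 random lists of the same size, matched in 20 bins of mean expression, and a list outside the central 95% counted as apart. This percentile is a description of these libraries. Of 33 such lists, 20 were apart for heart against liver, 18 for heart against kidney and 15 for kidney against liver, where lists of random genes would give 1.65. This is no test, since the lists share members and many hold markers of a single tissue or cell type.

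Genes named in the text were chosen by a rule fixed before the data were examined. It took the 12 genes highest in each library against both others among those with RPKM of at least 10 there, and the 6 lowest among those with RPKM of at least 10 in both others. It also took up to 4 members of each list described with the largest differences, the most abundant members of lists of other cells, the 5 most abundant genes of each library, Areg and the genes of the sort. Some genes this rule chose are not reported here. Further genes in the closing section belong to lists of proximal and distal nephron genes. Ccr2, of the monocyte-associated list, was added after the data were examined.

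Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter at RPKM of at least 5, scaling to a sum of 1000000 over genes (TPM), scaling by the median ratio to the geometric mean library, and random lists not matched on expression. Alternatives added after seeing the data were the transcript with the highest mean RPKM per gene, and leaving out genes in the lists of other cells, transcripts under 200 bp, or genes with over 2 reads per bp of exon in any library. The procedure was tested on simulated data. It found 100% of 100 genes made 8-fold higher, 0% of 100 genes made 2-fold higher and 0.0787% of 10160 unchanged genes past the 4-fold limit. These genes were drawn with Poisson error of the reads only, without noise from amplification. The procedure called 6.5% of 400 random lists apart, and 84% of 50 lists raised 2-fold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.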

Results

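Gene expression was measured by RNA sequencing in macrophages sorted from the heart, the liver and the kidney of C57BL/6 mice aged 8 weeks, with 1 library for each tissue. The sort kept cells carrying CD11b and F4/80, macrophage surface proteins encoded by Itgam and Adgre1, and left out cells carrying Ly6G or Ly6C, which mark neutrophils and inflammatory monocytes. The liver library is labelled as Kupffer cells, the resident macrophages of the liver sinusoids. The depth recovered from the deposited RPKM (reads per kilobase of exon per 1000000 reads counted) was 14460617 reads for the heart, 16743421 for the liver and 15550840 for the kidney library, over all transcripts. RPKM was at least 1 for 9061 genes in the heart, 9201 in the liver and 9923 in the kidney library. There were no replicates, so no difference was tested against variation between animals and every comparison describes these 3 libraries. Intervals of RPKM are exact 95% Poisson intervals of the read counts, and all intervals cover counting error only, since PCR copies were not told apart from independent molecules. The intervals also leave out the limit on tags counted at a position. If this limit held down densely read genes, such as Clec4f or F13a1, their folds would be understated by an unknown amount. A value with 1000 reads behind it had an interval from 93.9% to 106% of itself. Where a gene had 0 reads in a library, its fold is given as a lower bound against a floor of 3 reads in that library.

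Genes shared by tissue macrophages were abundant in all 3 libraries. The 20 pan-macrophage genes, such as Adgre1, Csf1r and Lyz2, all had RPKM of at least 1 in every library. Their median difference was -0.07 log2 units for heart minus liver (at percentile 71.5 of 10000 random lists matched on expression). It was 0.14 for heart minus kidney (at percentile 91.2) and -0.03 for kidney minus liver (at percentile 72.2). The sign for heart minus liver and for kidney minus liver depended on the scaling. Only 7 of these 20 genes had at most 2 reads per bp of exon in every library, and differences shrank among denser genes. For these 7 the differences of kidney minus heart ranged from -1.28 to 0.81 log2 units. Similar values of the denser genes therefore do not by themselves show equal expression. Adgre1, which is among the denser genes, stood at 427, 375 and 394 RPKM in the heart, liver and kidney library. Itgam, which shares 68.7% of its exon bases with another annotated gene, stood at 93.7, 27.9 and 38 RPKM. Ly6g, the neutrophil gene left out by the sort, had 2, 1 and 2 reads. The near-identical genes Ly6c1 and Ly6c2, whose reads may be shared, stood at 10.7, 10.1 and 14.5 RPKM and at 9.74, 8.41 and 5.58 RPKM. The most abundant genes included Cd74, the invariant chain of MHC class II, at 814, 764 and 1209.8 RPKM, and H2-Aa, an MHC class II chain, at 671, 478 and 751 RPKM. Lyz2, which encodes lysozyme, stood at 630.5, 626 and 428 RPKM, and Tmsb4x, which encodes an actin-binding peptide, at 692, 793 and 571 RPKM. B2m, the light chain of MHC class I, stood at 599, 621 and 581 RPKM and Wfdc17 at 430.4, 679.6 and 372 RPKM. Gm1821, annotated at 2 places in the genome, stood at 788, 848 and 788 RPKM, and its level is uncertain for that reason.

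Across the 11482 genes with RPKM of at least 1 in at least 1 library, the heart and kidney libraries were the most alike, with Pearson's r of 0.854 and Spearman's rho of 0.813 on log2(RPKM + 1). The values were 0.7898 and 0.738 for heart and liver, and 0.778 and 0.728 for kidney and liver. These are correlations across genes, and genes are not independent replicates. The median difference of all genes was -0.16 for heart minus liver, -0.23 for heart minus kidney and 0.04 for kidney minus liver. Scaling each library to a sum of 1000000 over genes (TPM) gave 0.00, -0.20 and 0.17, and scaling by the median ratio gave 0.00, -0.07 and 0.06, so the size of small differences depended on the scaling. The percentile of a list sets it against other genes of the same libraries and is therefore relative to this shift. Differences were smaller among genes densely covered with reads, such as Cd74, Lyz2 and Tmsb4x. The median absolute difference of heart and liver was 0.91 for the 608 genes with 1 to 2 reads per bp and 0.21 for the 40 genes with 5 to 6 reads per bp.

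**Figure D1:**
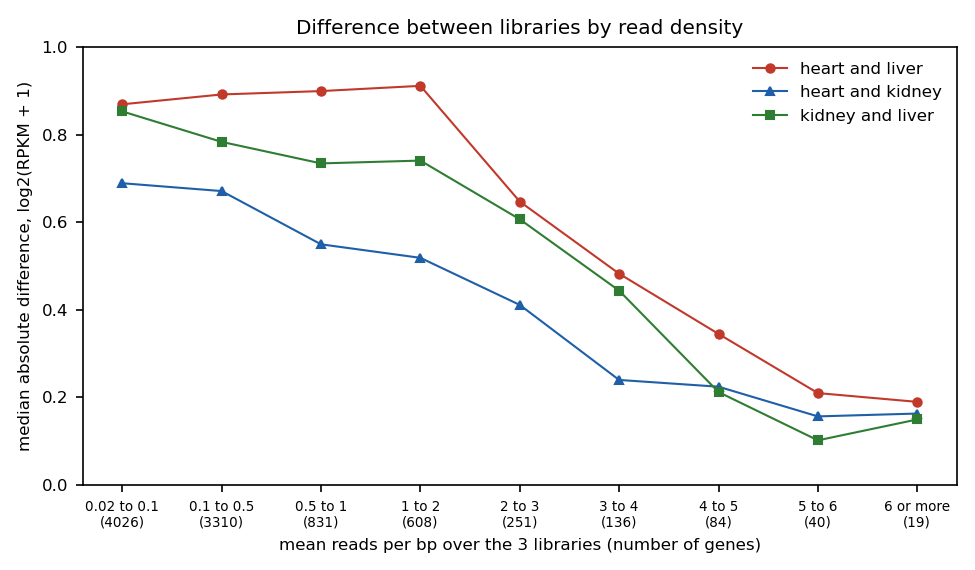
Median absolute difference between libraries on log2(RPKM + 1) against the mean number of reads per bp of exon over the 3 libraries, for genes of at least 500 bp, with the number of genes in brackets and 1 line for each pair of libraries. For heart and liver the median lies at 0.91 for 1 to 2 reads per bp and at 0.21 for 5 to 6 reads per bp.

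The heart library was compared with both others to find what sets cardiac macrophages apart, with Areg followed by name because amphiregulin from cardiac macrophages was taken, from general knowledge and not from the labels, as an interest of the study. Areg, which encodes the EGF receptor ligand amphiregulin, stood at 81.3 RPKM in the heart (95% interval 77.1 to 85.6, 1419 reads), 0 in the liver (0 reads) and 2.24 in the kidney library (42 reads). It was at least 548-fold higher in the heart than in the liver library and 36.3-fold higher than in the kidney library (counting interval 26.7 to 50.6). Areg ranked 13 among the genes highest in the heart library, after the 12 taken by the ranking. It lies on mm10 chromosome 5, 91139599 to 91148432. Retnla, which encodes the secreted protein RELMα, ranked highest in the heart library, at 329 RPKM (317 to 341) with 0 reads in both others, which made it at least 1087-fold and 1009.8-fold higher than in the liver and the kidney library. It lies on chromosome 16, 48842552 to 48844461. Csf2, which encodes the growth factor GM-CSF and shares 12% of its exon bases with another gene, stood at 110.4 RPKM, with 0 reads in both others. Emp1, a membrane protein, stood at 101 RPKM, Flrt3, a cell adhesion protein, at 36.4 and Slc10a6, a transporter of steroid sulfates, at 29.02, again with 0 reads in both others. F13a1, the A chain of coagulation factor XIII, stood at 422, 5.601 and 13.3 RPKM in the heart, liver and kidney library and was 75.3-fold (counting interval 67.9 to 83.8) and 31.7-fold (29.5 to 34.1) higher in the heart.

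The other leading heart genes were Ednrb, the endothelin receptor B, at 90.1, 0 and 0.123 RPKM, Steap4, a metalloreductase, at 45.6, 0 and 0.144, and S100a4, a calcium-binding protein, at 80.1, 0 and 1.56, in the order heart, liver and kidney. Clec4e, the pattern receptor Mincle, stood at 127, 3.14 and 0 RPKM, Cbr2, a carbonyl reductase, at 186, 5.49 and 4.96, and Tnip3, an inhibitor of NF-κB signalling, at 191, 5.895 and 5.03. S100a4 shares 51.7% of its exon bases with another gene. Of the 11 EGF receptor ligand genes, 4 passed the filter on low values, too few for a percentile. Beside Areg these were Hbegf at 36.2, 19.3 and 2.499 RPKM, Egf, known from the distal tubule of the kidney, at 0, 0.985 and 29.5 RPKM, and Nrg4 at 1.19, 0.031 and 0.805 RPKM. Genes lowest in the heart library included the interferon-inducible GTPases Gbp8 at 1.02, 89.2 and 29.4 RPKM and Gbp2b at 0.394, 169 and 14.98. The adhesion molecule Icam2 stood at 0.73, 17.98 and 22.5 RPKM, the MHC class I-like H2-M2 at 1.725, 33.1 and 32.6, the serine protease inhibitor Serpina3g at 0, 46.1 and 12.1 and the secreted nuclease Dnase1l3 at 5.305, 91.4 and 91.6. In total 144 genes were at least 4-fold higher and 145 at least 4-fold lower in the heart than in both other libraries. Of the 144 higher genes, 122 were protein coding and 8 belonged to the lists of other cell types, which hold only some genes of each type. With median ratio scaling the counts were 181 and 108, and with TPM they were 404 and 338. With pseudocounts of 0.1 and 5 they were 385 and 573, and 60 and 20.

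**Figure D2:**
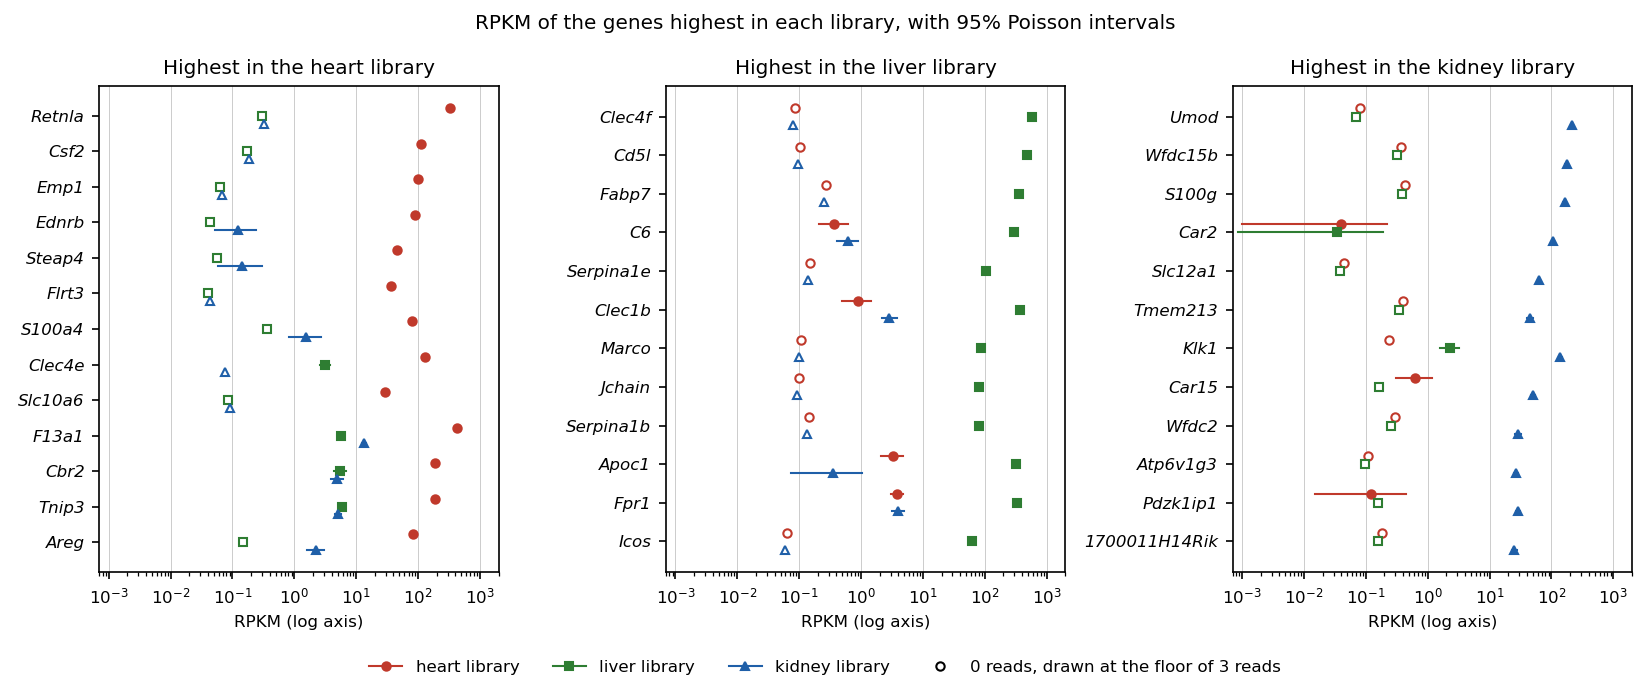
RPKM on a log axis of the 12 genes that rank highest in each library against both others, with Areg added for the heart, in the heart (circles), liver (squares) and kidney library (triangles). Lines are 95% Poisson intervals and open symbols stand for 0 reads, drawn at the floor of 3 reads. Retnla reaches 329 in the heart, Clec4f 572 in the liver and Umod 215 in the kidney library.

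The liver library was compared with both others to find what sets Kupffer cells apart. Clec4f, a lectin used as a Kupffer cell marker, stood at 572 RPKM (95% interval 565 to 579) with 0 reads in the heart and the kidney library, at least 6592-fold and 7089-fold higher than in these. It lies on mm10 chromosome 6, 83644542 to 83656116. Cd5l, a secreted inhibitor of macrophage apoptosis, stood at 472 RPKM, Fabp7, a fatty acid-binding protein, at 364 and Marco, a scavenger receptor, at 86.97, each with 0 reads in both others. C6, a component of the membrane attack complex, stood at 0.367, 296 and 0.615 RPKM in the heart, liver and kidney library and was 805-fold (counting interval 488 to 1438) and 481-fold (330.2 to 729.6) higher in the liver. Clec1b, the podoplanin receptor CLEC-2, stood at 0.893, 370.0 and 2.88 RPKM, Apoc1, an apolipoprotein, at 3.275, 317 and 0.351, and Fpr1, the formyl peptide receptor, at 3.83, 334 and 3.95.

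Genes of lymphocytes and hepatocytes stood beside them among the leading liver genes. Icos, a costimulatory receptor of T cells, stood at 62.6 RPKM and Jchain, the joining chain of secreted antibodies, at 81.95, with 0 reads in both other libraries. Serpina1e and Serpina1b, members of the near-identical antitrypsin genes of hepatocytes, stood at 103 and 81.04 RPKM, and which member the reads came from is uncertain. Of the 372 genes at least 4-fold higher in the liver than in both other libraries, 345 were protein coding and 31 belonged to the lists of other cell types. Icos, Jchain, Serpina1e and Serpina1b stand in none of these lists, so the count of 31 does not measure how much came from other cells. Another 296 genes were at least 4-fold lower in the liver than in both others. Among the lowest in the liver were the decoy interleukin 1 receptor Il1r2 at 162, 0 and 89.2 RPKM, the prostaglandin synthase Ptgs2 at 249, 0.054 and 32.5, and the costimulatory ligand Tnfsf9 at 283, 0.488 and 88.2. Serpinf1, which encodes PEDF, stood at 45.02, 0 and 56.5 RPKM, Mctp1 at 29.5, 0 and 26.8 and Serpinb8 at 89.2, 0.39 and 34.5. Tnfsf9 shares 14.9% of its exon bases with another gene. With TPM scaling, under which the pseudocount also weighs less, the counts were 567 higher and 833 lower. With median ratio scaling they were nearly even, at 332 higher and 337 lower. Which of these counts was the larger therefore depended on the setting. With pseudocounts of 0.1 and 5 the counts were 730 against 1054 and 121 against 62.

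The kidney library was compared with both others to find what sets renal macrophages apart, and genes known from the renal tubule led its highest genes. Umod, which encodes uromodulin of the thick ascending limb and shares 19.5% of its exon bases with another gene, stood at 215 RPKM (95% interval 211 to 219.9) with 0 reads in the heart and the liver library. It was at least 2724-fold and 3154-fold higher than in these and lies on mm10 chromosome 7, 119462708 to 119479262. Slc12a1, the sodium, potassium and chloride cotransporter of the same segment, stood at 63.4 RPKM and Atp6v1g3, a proton pump subunit of intercalated cells, at 26.7, with 0 reads in both others. S100g, a calcium-binding protein, stood at 163 RPKM, the protease inhibitor-like Wfdc15b and Wfdc2 at 176 and 29.04, Tmem213 at 45.2 and 1700011H14Rik at 25.2, likewise with 0 reads in both others. Car2, a carbonic anhydrase, stood at 105 RPKM with 1 read in each other library and was 2702-fold higher than in the heart (counting interval 485 to 106770). Klk1, a kallikrein of the distal tubule, stood at 0, 2.27 and 139.8 RPKM in the heart, liver and kidney library. Car15, another carbonic anhydrase that shares 65.7% of its exon bases with another gene, stood at 0.632, 0 and 49.9 RPKM, and Pdzk1ip1, a membrane protein of the tubule, at 0.123, 0 and 28.7. Of the 246 genes at least 4-fold higher in the kidney than in both other libraries, 220 were protein coding and 6 belonged to the lists of other cell types. Of the leading genes named here these lists hold only Umod and Slc12a1, so the count of 6 does not measure how much came from other cells.

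The 6 genes ranked lowest in the kidney library against both others were Il6, Timd4, Vsig4, Folr2, Ccl24 and Cd163. Il6, which encodes interleukin 6, had 0 reads in the kidney library and stood at 297 RPKM in the heart and 293 in the liver library, so it was at least 1743-fold and 1723-fold lower in the kidney. Timd4, a receptor for phosphatidylserine on apoptotic cells, stood at 148, 339.6 and 0 RPKM and Vsig4, a complement receptor, at 41.5, 455 and 0 in the heart, liver and kidney library. Folr2, a folate receptor that shares 63.1% of its exon bases with another gene, stood at 311, 355 and 2.1 RPKM, Ccl24, a chemokine for eosinophils, at 155, 241 and 1.05, and Cd163, the receptor for hemoglobin and haptoglobin, at 252, 243 and 5.68. Cd163 was 44.3-fold (counting interval 40.1 to 49.1) higher in the heart and 42.8-fold (38.8 to 47.4) higher in the liver than in the kidney library. In total 81 genes were at least 4-fold lower in the kidney than in both other libraries. With a pseudocount of 0.1 this count was 302, with a pseudocount of 5 it was 27, with TPM scaling 184 and without genes of over 2 reads per bp 53. The count of higher genes was 746, 53 and 677 with the pseudocounts of 0.1 and 5 and with TPM.

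Between the heart and the liver library, genes of Kupffer cells and complement were lower in the heart, and genes of matrix remodelling and inflammation were higher. The median of the 19 Kupffer cell genes was -4.93 log2 units for heart minus liver, below all 10000 random lists, with 15 genes at least 4-fold lower in the heart, led by Clec4f, Cd5l, Fabp7 and C6. Genes of liver sinusoidal endothelium differed alongside, with a median of -3.81 (below all 10000 random lists). Matrix remodelling genes had a median of 1.85 (above all 10000 random lists), or 1.81 with genes of 0 reads at the floor, and 10 of 22 were at least 4-fold higher in the heart. Among these was Thbs1, which encodes thrombospondin 1, at 18.4 RPKM against 0.072 in the liver. Spp1, which encodes osteopontin, stood at 70.8 RPKM against 7.64, and Timp1, a metalloproteinase inhibitor, at 7.21 against 0. Fibroblast and mural cell genes differed alongside the matrix genes, with a median of 1.27 (at percentile 99.95). Inflammatory cytokines and mediators had a median of 1.13 (at percentile 99.99), or 1.04 with genes of 0 reads at the floor. Here 4 of 16 genes were at least 4-fold higher in the heart, with Ptgs2 at 249 RPKM against 0.054 and Tnfsf9 at 283 against 0.488. The cytokine Osm stood at 29.45 RPKM against 0.408 and the interleukin 12 subunit Il12b at 12.1 against 0.622. Immediate early and heat shock genes differed alongside, with a median of 0.95 (above all 10000 random lists).

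Genes of the type I interferon response were lower in the heart than in the liver library, with a median of -1.42 (below all 10000 random lists). Irf7, a transcription factor of this response, stood at 2.62 against 159 RPKM, Ifi44 at 0 against 15.5, and the antiviral genes Oas1a and Oasl1 at 22.3 against 164 and 11.7 against 71.95. Of the 19 genes, 4 were at least 4-fold lower in the heart and 1 at least 4-fold higher. Genes of B cells and of T and NK cells differed alongside, with medians of -2.34 and -1.99. Complement genes had a median of -1.51 (below all 10000 random lists), with 8 of 18 at least 4-fold lower in the heart. C6 led them, with the complement regulator Cd59a at 0.558 against 34.3 RPKM, complement factor B (Cfb) at 4.18 against 95.9, and C4b at 1.36 against 30.4. Lipid handling genes had a median of -0.86 (at percentile 0.39), with 5 of 20 at least 4-fold lower in the heart. Apoc1 was among them, with the oxysterol receptor Nr1h3 at 1.07 against 104 RPKM, the fatty acid desaturase Scd1 at 1.203 against 62.2 and the cholesterol exporter Abcg1 at 11.6 against 85.7. Hepatocyte genes differed alongside these lists, with a median of -3.59. Immediate early and heat shock genes, which respond to cell handling and stimulation, were higher in the heart. Ier3 stood at 210.4 against 34.9 RPKM, the heat shock gene Hspa1b at 36.95 against 5.96, and the transcription factor genes Klf4 and Myc at 61.1 against 12.4 and 7.28 against 1.197.

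Further lists were higher in the heart than in the liver library. Pattern recognition genes had a median of 0.73 (at percentile 99.79). Clec4e was among them, with the flagellin receptor Tlr5 at 14.4 against 0.037 RPKM, the lipopeptide receptor Tlr2 at 294 against 34.7 and the adaptor Myd88 at 39.1 against 7.08. Chemokines had a median of 0.55 (at percentile 99.90) with members going both ways. The neutrophil chemokines Cxcl1 and Cxcl3 stood at 393 against 14.6 and 186 against 8.26 RPKM and Ccl9 at 275 against 32.7, while Cxcl13, a chemokine for B cells, stood at 7.18 against 348. Genes of resident cardiac and interstitial macrophages had a median of 0.65 (at percentile 99.81), with 6 of 18 at least 4-fold higher, led by Retnla, Ednrb and F13a1. Another 2 were at least 4-fold lower, among them the lectin Cd209g at 2.77 against 128. The CX3CR1 and microglia-associated genes had a median of 0.49 (at percentile 98.49). Among them were the Fc receptor-like Fcrls at 327 against 4.85 RPKM, Gpr34 at 181 against 26.1, Siglech at 15.5 against 1.69 and Gpr84 at 37.6 against 11.1. This list lay inside the range of random lists in 5 of the alternative settings. Monocyte-associated genes had a median of 1.18 (at percentile 99.95) over members going both ways. Higher in the heart were Cd209a at 270.1 against 0 RPKM and S100a4, and lower were the integrin Itgal at 5.67 against 98.5 and Ly6a at 24.4 against 229.9. Dendritic cell genes, among them Cd209a, differed alongside with a median of 0.83. With the filter at RPKM of at least 5 the monocyte-associated median was -0.33, inside the range of random lists (percentile 49.3). In total 612 genes were at least 4-fold higher and 819 at least 4-fold lower in the heart than in the liver library, of which 595 and 811 had a counting interval of the ratio beyond 2-fold. The balance depended on the scaling, with 1531 against 1266 genes under TPM and 758 against 676 under the median ratio. With pseudocounts of 0.1 and 5 the counts were 1582 and 1686, and 194 and 271, and without genes of over 2 reads per bp the lipid list lay inside the range of random lists.

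Between the heart and the kidney library, the lists of resident macrophage genes, monocyte-associated genes and inflammatory mediators had higher medians in the heart. The 18 genes of resident cardiac and interstitial macrophages had a median of 3.46 log2 units for heart minus kidney (above all 10000 random lists), and 10 were at least 4-fold higher in the heart. Lyve1, the hyaluronan receptor of this list, stood at 336 RPKM in the heart against 0 in the kidney library, at least 4527-fold higher, beside Retnla, Timd4 and Folr2. Inflammatory cytokines and mediators had a median of 1.62 (above all 10000 random lists), with 7 of 16 at least 4-fold higher in the heart. Besides Il6 these included Ifnb1, which encodes interferon beta, at 184 against 4.02 RPKM, the interleukin 1 receptor antagonist Il1rn at 271 against 6.37 and the anti-inflammatory cytokine Il10 at 273 against 10.9. Monocyte-associated genes had a median of 1.54 (above all 10000 random lists), or 1.48 with genes of 0 reads at the floor. Of 14 genes 5 were at least 4-fold higher and 2 at least 2-fold lower in the heart. S100a4 led the higher genes, with Cd209a at 270.1 against 10.9 RPKM, Plac8 at 129 against 5.69 and the chitinase-like Chil3 at 4.89 against 0. Itgal stood at 5.67 against 19.8 RPKM and Ly6a at 24.4 against 88.97. Ccr2, also of this list, stood at 117 against 227 RPKM, so its members went both ways.

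Chemokines had a median of 0.74 for heart minus kidney (above all 10000 random lists), with 6 of 21 at least 4-fold higher in the heart. Among these were Ccl24, Cxcl3 at 186 against 11.8 RPKM and Ccl22 at 26.6 against 1.602, while the interferon-inducible Cxcl9 stood at 4.17 against 45.1. The interferon response list was lower in the heart, with a median of -0.89 (at percentile 0.07). Irf7 stood at 2.62 against 37.9 RPKM, Ifi44 at 0 against 7.101 and Oas1a at 22.3 against 92.6, whereas Ifit1 stood at 135 against 21.8. MHC class II genes were lower in the heart, with a median of -0.57 (at percentile 0.64). H2-Oa stood at 2.46 against 45.5 RPKM, the class II transactivator Ciita at 1.45 against 23.6 and H2-DMb2 at 52.02 against 168, while the costimulatory ligand Cd80 stood at 49.3 against 3.68. Matrix remodelling genes had a median of 0.57 (above all 10000 random lists), with 5 of 22 at least 4-fold higher and 2 at least 2-fold lower in the heart. Among the higher genes were the metalloproteinases Mmp19 at 18.2 against 0.965 RPKM and Adamts1 at 5.34 against 0, Timp1 and Thbs1, while Spp1 stood at 70.8 against 180.3 and Mmp12 at 69.75 against 183. Fibroblast and mural cell genes differed alongside, with a median of 1.18 (at percentile 99.99), Dcn at 125 against 0.48 RPKM and Lum at 21.01 against 0. Iron and heme handling genes had a median of 0.38 (at percentile 99.55). Cd163 led them, with the ferroxidase ceruloplasmin (Cp) at 51 against 2.85, the heme-binding repressor Bach1 at 44.6 against 5.26 and the transferrin receptor Tfrc at 4.904 against 0.815. Erythroid genes had a median of -1.55 in the same comparison.

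The CX3CR1 and microglia-associated genes had a median of 0.57 for heart minus kidney (at percentile 99.84). The largest differences were those of Fcrls at 327 against 39.9 RPKM, Gpr84 at 37.6 against 5.57, the matrix protein gene Sparc at 11.1 against 1.64 and Tmem119 at 1.07 against 5.36. Macrophage transcription factors had a median of 0.30 (at percentile 98.48). The largest differences were those of Bhlhe40 at 47.02 against 12.6, Cebpb at 52.9 against 19.7, Irf8 at 10.65 against 26.05 and Id1 at 1.49 against 0.138. Pattern recognition genes had a median of 0.24 (at percentile 97.51). Beside Clec4e stood the receptor of double-stranded RNA Tlr3 at 2.26 against 13.3 RPKM, the inflammasome sensor Nlrp3 at 112 against 26.3 and Tlr8 at 47.6 against 13.9. In total 275 genes were at least 4-fold higher and 586 at least 4-fold lower in the heart than in the kidney library, of which 263 and 565 had a counting interval of the ratio beyond 2-fold. With pseudocounts of 0.1 and 5 and with TPM the counts were 751 and 1599, 108 and 105, and 685 and 1293. Without genes of over 2 reads per bp the lists of MHC class II, iron, CX3CR1-associated and pattern recognition genes lay inside the range of random lists, the last with a median of -0.13 (percentile 59.3). The MHC class II list also lay inside the range with random lists not matched on expression, the pattern recognition list also with a pseudocount of 0.1 and with TPM, and the transcription factor list in 4 of the alternative settings.

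Between the kidney and the liver library, Kupffer cell, complement and iron handling genes were lower in the kidney, and immediate early, MHC class II and matrix genes were higher. The 19 Kupffer cell genes had a median of -6.46 log2 units for kidney minus liver (below all 10000 random lists), or -6.32 with genes of 0 reads at the floor, and 17 were at least 4-fold lower in the kidney. Genes of liver sinusoidal endothelium differed alongside here too, with a median of -2.43. Clec4f and Cd5l led the Kupffer cell list, with Vsig4 and the ficolin Fcna at 0 against 406 RPKM. Immediate early and heat shock genes had a median of 1.32 (above all 10000 random lists). Among them were the cochaperone Dnajb1 at 142 against 6.95 RPKM, Myc at 33.4 against 1.197, Hspa1b at 30.7 against 5.96 and Ier3 at 125 against 34.9. MHC class II genes had a median of 0.65 (at percentile 99.74), with Ciita at 23.6 against 4.29 RPKM and H2-Ob at 32.8 against 13.1, while Cd80 stood at 3.68 against 14.4 and the lysosomal reductase Ifi30 at 109.7 against 285. Dendritic cell genes differed alongside, with a median of 1.30. Matrix remodelling genes had a median of 0.83 (at percentile 99.68), or 0.82 with genes of 0 reads at the floor. Among them were Spp1 at 180.3 against 7.64 RPKM, the macrophage elastase Mmp12 at 183 against 9.47 and the gelatinase Mmp9 at 0 against 4.76.

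Complement genes had a median of -0.58 for kidney minus liver (at percentile 1.41), with 7 of 18 at least 4-fold lower in the kidney. Vsig4 and C6 led this list, with Cfb at 2.71 against 95.9 RPKM and C4b at 0.649 against 30.4. Hepatocyte genes differed alongside, with a median of -3.30 (below all 10000 random lists). Iron and heme handling genes had a median of -0.57 (at percentile 1.73), with 4 of 19 at least 4-fold lower. Among these were Cd163, the heme transporter Slc48a1 at 4.85 against 47.4 RPKM, Tfrc at 0.815 against 7.42 and the heme-binding protein Hebp1 at 9.51 against 43.3. Cell cycle genes had a median of -0.71 (at percentile 0.99). Among them were the mitotic kinase Cdk1 at 5.19 against 26.7 RPKM, Birc5 at 2.51 against 13.2 and the replication helicase subunit Mcm6 at 6.31 against 20.9, whereas the cyclin gene Ccnb2 stood at 8.87 against 0.82. Genes of B cells and of T and NK cells differed alongside, with medians of -2.06 and -2.33. The CX3CR1 and microglia-associated genes had a median of 0.72 (at percentile 99.28). Higher in the kidney were Fcrls at 39.9 against 4.85 RPKM and Gpr34 at 113 against 26.1, while the nucleotide receptor P2ry13 stood at 41.7 against 199. In total 869 genes were at least 4-fold higher and 586 at least 4-fold lower in the kidney than in the liver library, of which 843 and 578 had a counting interval of the ratio beyond 2-fold. With pseudocounts of 0.1 and 5 and with TPM the counts were 2023 and 1155, 203 and 188, and 1986 and 932. The complement, iron, matrix and cell cycle lists lay inside the range of random lists in 2, 4, 3 and 2 of the alternative settings. The CX3CR1 list did so without genes of over 2 reads per bp and with random lists not matched on expression, and the MHC class II list with the latter.

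**Figure D3:**
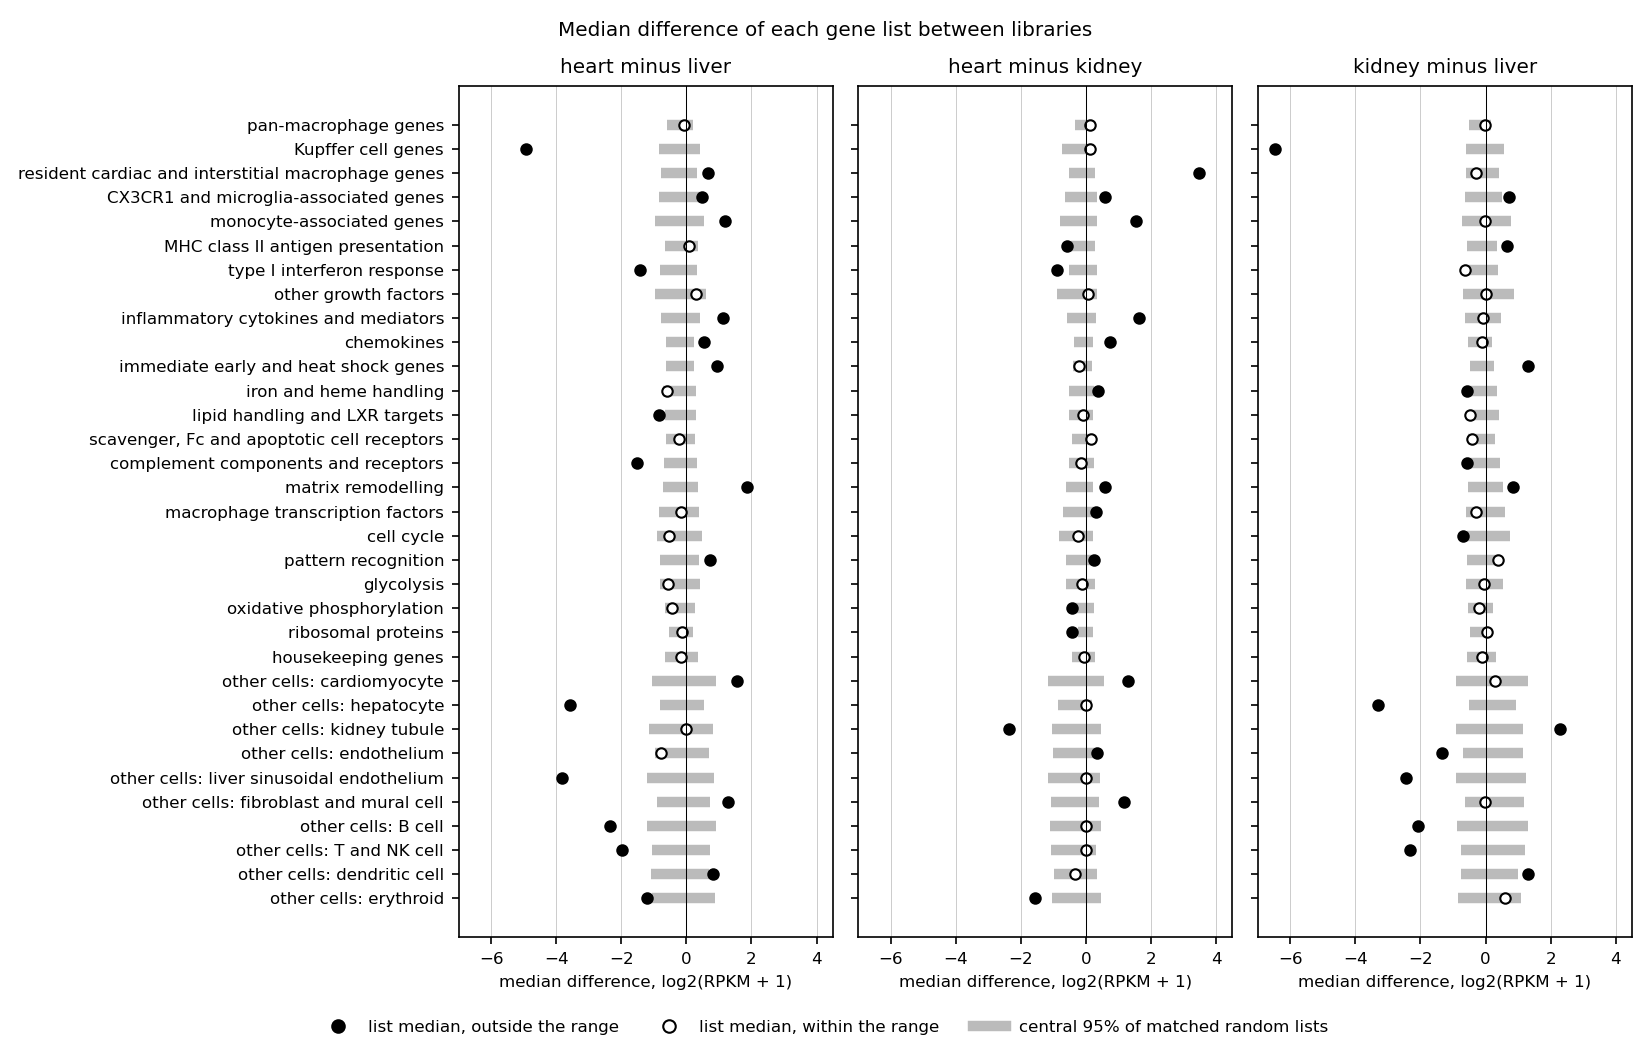
Median difference on log2(RPKM + 1) of each gene list for heart minus liver, heart minus kidney and kidney minus liver. Grey bars span the central 95% of 10000 random lists matched on expression, and filled points lie outside it. Kupffer cell genes lie at -4.93 for heart minus liver and at -6.46 for kidney minus liver, and resident cardiac and interstitial macrophage genes at 3.46 for heart minus kidney.

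Several lists of other cell types followed the tissue of origin. Kidney tubule genes had a median of -2.37 for heart minus kidney (below all 10000 random lists) and 2.30 for kidney minus liver (above all 10000 random lists), or -1.94 and 2.09 with genes of 0 reads at the floor, led by Umod and Slc12a1. Of the genes of each list in the table, 3 of 19 tubule, 1 of 20 hepatocyte, 3 of 11 sinusoidal endothelial, 0 of 20 cardiomyocyte and 2 of 16 fibroblast genes had RPKM of at least 1 in all 3 libraries. Only 9 tubule, 18 hepatocyte, 9 sinusoidal endothelial and 8 cardiomyocyte genes passed the filter on low values. All of these had RPKM of at least 1 in the library of their own tissue, so the filter itself favoured the direction of these medians. For heart minus liver the tubule median was 0.00 (at percentile 61.6). Hepatocyte genes had a median of -3.59 for heart minus liver and -3.30 for kidney minus liver, both below all 10000 random lists, or -3.49 and -3.18 with genes of 0 reads at the floor. For heart minus kidney it was 0.00. Their most abundant member, the transferrin gene Trf, stood at 388, 384 and 382 RPKM in the heart, liver and kidney library, and the albumin gene Alb at 0, 64.3 and 0.22. Trf is densely read, so its similar values do not by themselves show equal expression. Genes of liver sinusoidal endothelium had a median of -3.81 for heart minus liver and -2.43 for kidney minus liver, both below all 10000 random lists, and 0.00 for heart minus kidney. The lectin gene Clec4g stood at 1.24, 129 and 0 RPKM and the hyaluronan receptor gene Stab2 at 0, 57.5 and 0. Cardiomyocyte genes had a median of 1.55 for heart minus liver (at percentile 99.97), 1.28 for heart minus kidney (at percentile 99.96) and 0.28 for kidney minus liver, or 1.44 and 1.07 for the heart with genes of 0 reads at the floor. Their most abundant members Myl2, a myosin light chain, and Tnni3, cardiac troponin I, stood at 5.98, 0 and 3.61 RPKM and at 3.65, 0 and 0.474 RPKM in the heart, liver and kidney library. Fibroblast and mural cell genes had a median of 1.27 (at percentile 99.95), 1.18 (at percentile 99.99) and -0.02 in the same order, or 1.23 and 1.15 for the heart with genes of 0 reads at the floor. Of the 12 fibroblast genes compared, 10 had RPKM of at least 1 in the heart, 6 in the liver and 3 in the kidney library. Here too the filter favoured the direction. The proteoglycan genes Dcn and Lum stood at 125, 8.15 and 0.48 RPKM and at 21.01, 0 and 0 RPKM, and the matrix protein gene Mgp at 20.4, 0 and 1.52.

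Genes of blood and endothelial cells differed as well. B cell genes had a median of -2.34 for heart minus liver (below all 10000 random lists) and -2.06 for kidney minus liver (at percentile 0.01). Cd79b, a chain of the B cell receptor, stood at 32.9, 170.3 and 168 RPKM in the heart, liver and kidney library and Cd79a at 0.524, 34.1 and 0.049. T and NK cell genes had medians of -1.99 (at percentile 0.02) and -2.33 (below all 10000 random lists), or -2.15 for the latter with genes of 0 reads at the floor. Granzyme A (Gzma) stood at 5.399, 24.3 and 0 RPKM and Cd3g at 0, 16.7 and 0. For heart minus kidney the medians of these lists were 0.00 and 0.00. All 9 B cell genes compared had RPKM of at least 1 in the liver library, against 3 in the heart and 2 in the kidney library. Of 11 T and NK cell genes compared these numbers were 9, 7 and 4. The filter on low values thus favoured the direction of these medians as well. Of 15 dendritic cell genes, 7 had RPKM of at least 1 in all 3 libraries and 4 stand in another list. Dendritic cell genes had a median of 0.83 for heart minus liver (at percentile 98.82), -0.34 for heart minus kidney and 1.30 for kidney minus liver (at percentile 99.49), with the lectin Cd209a at 270.1, 0 and 10.9 RPKM. Endothelial genes had a median of -0.79 for heart minus liver, 0.34 for heart minus kidney (at percentile 97.62) and -1.34 for kidney minus liver (at percentile 0.03), or -1.26 for the latter with genes of 0 reads at the floor. Fabp4, a fatty acid-binding protein, stood at 139, 30 and 3.85 RPKM and Pecam1, the adhesion molecule CD31, at 3.15, 25.8 and 7.895. Erythroid genes had a median of -1.20 for heart minus liver (at percentile 1.3), -1.55 for heart minus kidney (at percentile 0.01) and 0.61 for kidney minus liver. The globin genes Hbb-b1 and Hba-a1, whose near-identical copies may share reads, stood at 12.3, 119 and 35.95 RPKM and at 15.6, 37.2 and 57.1 RPKM. Of the 9 erythroid genes compared, 6 were such globin genes, with Hba-a2 at 15.5, 36.4 and 56.6 RPKM. The list thus holds fewer independent values than the random lists of 9 genes, and its percentiles may overstate how far it lies apart. With a pseudocount of 0.1 the erythroid list lay inside the range of random lists for heart minus liver. Lists with fewer than 5 genes compared got no percentile. Their most abundant members were Il1r2, Csf3r at 11.8, 31.6 and 17.8 RPKM and S100a8 at 4.11, 0 and 0 for neutrophils. For mast cells, basophils and eosinophils the eotaxin receptor gene Ccr3 stood at 2.71, 33.2 and 0.039 RPKM, and for platelets the chemokine gene Ppbp at 54.3, 0 and 1.44. The dendritic cell list lay inside the range of random lists in 3 of the alternative settings for heart minus liver and in 2 for kidney minus liver, and the endothelial list in 6 for heart minus kidney and in 1 for kidney minus liver.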

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

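The heart and kidney libraries were the most alike in every setting of pseudocount, filter, scaling, transcript and genes left out, with the gap of Pearson's r to the next pair at 0.0642 as reported. Of 1047 list medians recomputed, 981 kept their side of the random lists, 47 moved inside with the same sign, 2 moved inside with a changed sign and 17 moved outside. Under TPM or median ratio scaling, or relative to the median of all genes, 0 medians of lists that were apart and 14 of others changed sign, among these housekeeping genes in all 3 comparisons and pan-macrophage genes in 2. Of 1866 values of named genes 480 moved by more than counting error, or at all where a library had 0 reads, and 0 changed sign among differences of at least 4-fold. Of 120 counts of genes, 83 stayed within 1.5 times the reported count. The alternatives on transcripts, on genes of other cells, on transcripts under 200 bp and on genes over 2 reads per bp were chosen after the data were seen. No paired analysis was possible because each tissue has 1 library, and leaving out a library was not possible for the same reason. The floor of 3 reads limits what can be said of genes without reads, and with these at the floor the counts of genes at least 4-fold higher in heart, liver and kidney than in both others were 127, 349 and 225, and of lower genes 140, 276 and 75.

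With a pseudocount of 0.1, 1582 genes were higher in heart than liver and 1686 the reverse, 751 in heart than kidney and 1599 the reverse, and 2023 in kidney than liver and 1155 the reverse, while 385, 730 and 746 were higher and 573, 1054 and 302 lower in heart, liver and kidney than in both others. The gap was 0.0733. With a pseudocount of 5, 194 genes were higher in heart than liver and 271 the reverse, 108 in heart than kidney and 105 the reverse, and 203 in kidney than liver and 188 the reverse, while 60, 121 and 53 were higher and 20, 62 and 27 lower in heart, liver and kidney than in both others. The gap was 0.0548. A pseudocount shrinks the differences of genes with low values, so a larger one leaves fewer genes past 4-fold by construction. With TPM scaling, 1531 genes were higher in heart than liver and 1266 the reverse, 685 in heart than kidney and 1293 the reverse, and 1986 in kidney than liver and 932 the reverse, while 404, 567 and 677 were higher and 338, 833 and 184 lower in heart, liver and kidney than in both others. The gap was 0.0524. This scaling multiplies the values by 3.64, 3.21 and 3.49, so that more genes pass the filter (13244) and the pseudocount weighs less.

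Without the filter the gap was 0.0348, with the filter at RPKM of at least 5 it was 0.1057 and without genes over 2 reads per bp 0.0898. For these the cause was not tested. Without genes of other cells 11 lists were apart for heart against liver and 8 for kidney against liver, since the lists of these cells were left out, while the CX3CR1 list also moved inside for heart against liver. The cause of that was not tested. Without genes over 2 reads per bp, 9 lists were apart for heart against kidney and 53 genes were lower in the kidney than in both others, with fewer genes compared (10540). The monocyte-associated median for heart minus liver was -0.33 with the filter at RPKM of at least 5, and the pattern recognition median for heart minus kidney was -0.1324 without genes over 2 reads per bp. Both lay inside the range of random lists (percentiles 49.3 and 59.3). In both the list held fewer genes, and the cause was not tested further.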

Other observations

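The tests of the tag limit, of depth and of fewer macrophages below were chosen after the results were seen.

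Genes of protein synthesis and respiration were lower in the heart than in the kidney library, where the median of all genes was -0.23 and that of kidney tubule genes -2.37. Ribosomal protein genes had a median of -0.43 log2 units for heart minus kidney (at percentile 0.04), -0.14 for heart minus liver and 0.05 for kidney minus liver, with Rpl18 at 37.6, 153 and 159 RPKM in the heart, liver and kidney library and Rplp1 at 104, 47.3 and 203. Genes of oxidative phosphorylation had a median of -0.44 for heart minus kidney (at percentile 1.75), -0.44 for heart minus liver and -0.19 for kidney minus liver, with the complex III gene Uqcrc1 at 21.3, 4.33 and 83.98 RPKM and the complex I gene Ndufv1 at 6.28, 22.4 and 30.8. For heart minus kidney the first of these lists lay inside the range of random lists with lists not matched on expression, and the other in 3 of the alternative settings. Glycolysis genes had medians of -0.57, -0.11 and -0.06 for heart minus liver, heart minus kidney and kidney minus liver, none of them apart from random lists, with the regulator Pfkfb3 at 51, 0.463 and 9.52 RPKM. Housekeeping genes had medians of -0.18, -0.06 and -0.11, with the polymerase factor gene Tbp at 10.5, 15.5 and 21.6 RPKM, and the sign of each depended on the scaling.

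Other growth factors had medians of 0.30, 0.05 and 0.00 in the same order, with Igf1, insulin-like growth factor 1, at 68.8, 153 and 16.04 RPKM and Pdgfb, a platelet-derived growth factor, at 3.51, 1.67 and 20.6. Scavenger, Fc and apoptotic cell receptors had medians of -0.22, 0.16 and -0.42. Cell cycle genes had medians of -0.54 for heart minus liver and -0.24 for heart minus kidney. Of the lists described above, those not apart in a comparison had medians of -0.63 for interferon response, -0.09 for inflammatory mediators, -0.10 for chemokines, -0.30 for resident macrophage and -0.03 for monocyte-associated genes in kidney minus liver. For heart minus kidney these were 0.13 for Kupffer cell, -0.22 for immediate early, -0.09 for lipid and -0.16 for complement genes, and for heart minus liver 0.09 for MHC class II, -0.59 for iron handling and -0.18 for transcription factor genes. The Y-linked genes Ddx3y and Eif2s3y stood at 79.2, 44.6 and 40.4 and at 97.9, 45.1 and 59.95 RPKM, and Xist, the RNA of the inactive X chromosome, at 0, 0 and 0.004. With 4 sex-linked genes compared, this list got no percentile.

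Differences between libraries shrank among genes densely covered with reads, such as Cd74 and Tmsb4x. Poisson counting error alone of the less abundant genes was excluded, since Poisson draws with equal means gave a median absolute difference of 0.0524. This was for heart and liver at 0.1 to 0.5 reads per bp, where 0.8917 was observed. The draws took each read as an independent molecule, so added noise from amplification was not tested. Genes were grouped by their mean reads per bp over the 3 libraries, so a gene dense in 1 library alone falls in a lower group. The densest groups hold mostly genes dense in all 3, and part of the drop is set by this grouping. How large that part is was not tested. The limit on tags per position stays open. At 6 or more reads per bp the median was 20.8% of that at 1 to 2 reads per bp, but 22, 43 and 18 genes in the heart, liver and kidney library lay above 6 reads per bp, the ceiling that 3 tags per position on 2 strands would set, and the highest reached 18.8 reads per bp. Whether abundant genes differ less between these tissues was not tested.

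Genes of the kidney tubule led the genes higher in the kidney library, although the sort for CD11b and F4/80 should remove tubule cells. RNA or cells of the distal nephron may account for this, since 17 of 20 further distal nephron genes had at least 3 reads in the kidney library and more RPKM there than in both others, with Kng2 at 28.1, Atp6v0d2 at 10.7 and Cldn10 at 10.04 RPKM in the kidney. RNA of the whole tubule stays open as well, since the median of 10 proximal genes was 0.2152 times that of the distal genes, above the 0.1 set beforehand (0.3575 against 1.6615 RPKM). Of these 10, 5 met the same conditions as the 17, Gatm and Slc13a3 among them. Gatm and Slc13a3 were also read in the heart library, at 212 and 12.5 RPKM, so they are not markers of the tubule here. Both the median and the count of 5 include them and are therefore weak evidence for proximal RNA. Proximal genes of the fixed tubule list were mostly low in the kidney library. Slc22a6, Slc22a8, Miox and Slc27a2 stood at 0 RPKM, Lrp2 at 0.451 and Slc34a1 at 0.65, while Kap stood at 4.17 and Gpx3 at 27.3. These values come from 1 library and do not decide the question. Expression of such genes in renal macrophages themselves was not tested.

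Genes such as Il6, Timd4 and Cd163 were lower in the kidney library than in both others, with a median of -2.8099 log2 units for kidney minus heart over 81 genes. Each of the 81 was chosen as at least 2 log2 units lower, so this median was bounded by the choice. Lower depth was excluded, since the kidney library held 1.0754 times the reads of the heart library. Fewer macrophages in the kidney library, as the whole cause, would lower pan-macrophage genes by as much. The 7 pan-macrophage genes with at most 2 reads per bp argue against that, with a median of -0.3635 for kidney minus heart and the lowest at -1.2801. Their 95% interval over members, from -1.1306 to 0.5455, covers the spread between these genes and not between animals. A different mix of macrophage subsets and the tissue itself stay open, and neither was tested.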
